A study of Mus musculus with 2 samples.

How the data were processed

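MicroRNA-seq of liver from mouse embryos at day 12.5 (strain B6NCrl, sexes pooled) was analysed in 2 biological replicates, made from pools of 120 and 88 embryos. The labels give both pools the same donor identifier, so that they are biological replicates rests on their replicate numbers, separate tissue sample identifiers and pool sizes, and the SD may in part be technical. Per the labels, both are libraries of short RNA, and the extraction protocol is not given in the sources used here. The labels assign both libraries to a single group, so no comparison of conditions was made.

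The authors deposited a table of raw read counts per library, with 1973 annotated miRNA genes. Per the files' own lists, the reads were aligned to mm10 and counted against GENCODE M4. The aligner, the counter and their versions are not given in the sources used here. Each table has counts for both strands together, for the sense strand and for the opposite strand, and 4 lines of reads that belong to no gene. Those lines held 29.4% and 25.8% of the reads as unmapped (replicates 1 and 2), 28.8% and 31.1% as aligned to several places, 10.6% and 11.0% as on the sense strand of no listed gene, which takes in the opposite-strand counts below, and at most 1 read as ambiguous. They were left out of library sizes and tests. Reads aligned to several places made up 40.8% and 41.9% of all aligned reads, so miRNAs encoded by several identical genes can be undercounted in these tables. The depth was 11057424 and 11013976 reads, of which 31.2% and 32.1%, or 3447858 and 3534816, were sense counts on miRNA genes. Opposite-strand counts came to 374792 and 363712. With this depth a count of 0, taken as at most 3 counts, allows 0.870 and 0.849 CPM.

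Gene names, coordinates and host genes came from GENCODE M21, which is on the same assembly. Of the 1973 listed identifiers, 1894 were found there, 1815 in the same version and 79 in another version. A further 79 were not found in M21, and these held 3 sense counts in all. Of the miRNA genes of M21, 308 are not analysed here by sense counts, and 32 of these overlap a listed gene on the other strand. A gene was called uncertain when its hairpin shares a run of 20 bases with a miRNA gene at another place, which held for 929 listed genes, 105 of them with at least 10 counts. This stood in for a comparison of mature sequences, which were not used here, and the shared run can lie outside the mature miRNA. Such genes held 10.6% ± 0.385 (SD, n = 2) of the counts.

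Sense counts were scaled to counts per 1000000 sense counts on miRNA genes (CPM). A gene was detected at 10 CPM in both libraries. Differences between the 2 libraries were tested for 464 genes with at least 10 counts over both, by a two-sided exact binomial test against library sizes scaled by TMM, with Benjamini-Hochberg adjustment at 0.05. A log2 ratio is replicate 2 over replicate 1 with 0.5 counts added, and its 95% interval is the exact Clopper-Pearson one. This test allows for counting error only. The biological coefficient of variation was estimated from both libraries with an intercept-only design in edgeR, and edgeR's negative binomial exact test was run with 0.1 and with the estimate. Each side of that test is 1 library, and the estimate comes from the difference it is set against, so with the estimate it only ranks genes against the spread of the others. For each list, the median log2 ratio was placed among 10000 random lists matched on level, each member replaced by one of the 20 nearest other genes. On simulated counts with 200 changed genes, 468 genes were tested, 273 of them unchanged. The binomial test called 43.75% of genes changed 1.2-fold, 57.1% changed 1.5-fold, 85.7% changed 2-fold and 91.8% changed 4-fold in the right direction. It also called 2.56% of unchanged genes. That simulation held counting noise only.

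The lists were fixed before the data were examined. There were 19 with 156 members, of which 143 were analysed (5 matched through RefSeq synonyms) and 13 were not analysed here. They cover hepatocyte, erythroid, blood leukocyte and megakaryocyte, endothelial, mesenchyme and smooth muscle, epithelial miR-200, miR-192 and miR-194, the clusters miR-17-92, miR-106b-25 and miR-106a-363, let-7, the imprinted Dlk1-Dio3 and H19 and Igf2 miRNAs, brain, heart and skeletal muscle, pancreas, pluripotent cell, airway, and eye, ear and sensory miRNAs. The miR-183 cluster is the sensory list. Genes were named by a rule fixed at the same time. It took the 15 highest by mean CPM, the 3 highest of each list with every member of a list of 4 or fewer, and the 5 largest log2 ratios in each direction among genes with at least 100 counts that passed the exact test. Other genes named were chosen after their values were seen: further list members given as examples, the unlisted genes opposite a listed gene, and the genes of the other observations.

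Alternatives fixed beforehand were the counts of both strands, other detection thresholds, scaling without the top gene or to all reads, and leaving out genes whose mature sequence has another copy. For the last of these, genes that share 20 bases were left out instead. Also fixed were DESeq2 size factors or total counts in place of TMM, filters of 1 and 100 counts, pseudocounts of 0.1 and 10 CPM, the negative binomial test at 0.1, and each replicate alone. Opposite-strand counts given to the unlisted gene, and the negative binomial test with the estimated variation, were added after the data were seen. The tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.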

Results

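Short RNA was sequenced from the liver of mouse embryos at day 12.5, when this organ is a main site of blood formation as well as of hepatoblast growth. The mice were of strain B6NCrl, males and females were pooled, and there were 2 biological replicates of a single group. Replicate 1 held the livers of 120 embryos and replicate 2 those of 88. The labels name no second tissue, age or treatment, so the values below are miRNA levels in embryonic liver, their spread over the 2 replicates and the differences between the 2 libraries. The libraries held 11057424 reads (replicate 1) and 11013976 reads (replicate 2), of which 3447858 and 3534816 were counted on the sense strand of annotated miRNA genes. Levels are counts per 1000000 of those sense counts (CPM), given as mean ± SD. An SD from n = 2 is itself imprecise. The counts carry no molecular identifiers, so every interval and limit given covers counting error only.

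By uniquely aligned sense counts, the most abundant miRNA genes of day 12.5 liver included miRNAs known from endothelial cells, hepatocytes, proliferating cells and imprinted loci. Mir126a, an endothelial miRNA, led with 68490 ± 461 CPM (SD, n = 2), or 6.85% of all miRNA gene counts. Mir122, the miRNA typical of hepatocytes, followed at 54020 ± 9747 CPM. Mir17, of the growth-promoting miR-17-92 cluster, stood at 50882 ± 4321 CPM. Mir335, carried by the imprinted gene Mest, stood at 50413 ± 3779 CPM. The differences among Mir122, Mir17 and Mir335 lay within the SD of Mir122, and the order of these 3 genes was not the same in the 2 libraries. Reads aligned to several places are left out, so miRNAs encoded by several identical genes can rank too low. With opposite-strand counts given to the M21 gene on that strand, Mir142 would rank 5 and Mir409 rank 9.

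In mm10 coordinates of the GENCODE M21 annotation, Mir126a (ENSMUSG00000065540.1) spans chromosome 2, 26591357 to 26591429, on the plus strand, and overlaps an exon of the endothelial gene Egfl7. Mir122 (ENSMUSG00000065402.1) lies on chromosome 18, 65248861 to 65248926, in an exon of the long noncoding RNA AC157910.3. Mir17 (ENSMUSG00000065508.1) lies on chromosome 14, 115043671 to 115043754, in an exon of Mir17hg. Mir335 (ENSMUSG00000065501.1) lies on chromosome 6, 30741299 to 30741396, in an intron of Mest. The next genes by mean level were Mir26b, in an intron of Ctdsp1, at 39951 ± 2548 CPM, Mir322 at 30861 ± 684 CPM and Mirlet7g, in an intron of Wdr82, at 29605 ± 2140 CPM. Mir21a, Mir99a, Mir411, Mir451a, Mir20a, Mir130a, Mir431 and Mir143 completed the top 15, with means between 19685 CPM for Mir143 and 25499 CPM for Mir21a. Mir411 shares a run of at least 20 bases with Mir758, so its level is uncertain.

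A small part of the annotated genes carried nearly all counts. Of 1973 annotated miRNA genes, 301 reached 10 CPM in both libraries, and 464 did so at a threshold of 1 CPM. A further 1219 genes had 0 counts in both libraries, which allows up to 0.870 CPM of uniquely aligned reads in replicate 1 and 0.849 CPM in replicate 2. For genes that share 20 bases with another locus this does not bound the level of the mature miRNA. The 10 most abundant genes held 39.8% ± 0.682 (SD, n = 2) of the counts, the top 50 held 84.0% ± 0.575 and the top 100 held 95.4% ± 0.0776. With all reads of the library as the denominator, the share of the top 10 was 12.6%.

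Cell type markers fixed before the data were examined placed endothelial, mesenchymal, hepatocyte and erythroid miRNAs among the abundant ones. Whether these miRNAs came only from the cells their list is named for was not tested, so the shares do not measure cell type content. The endothelial list (Mir126a, Mir10a and Mir10b measured) held 7.97% ± 0.0237 (SD, n = 2) of the counts, with 6.85% on Mir126a, 9444 ± 584 CPM for Mir10a and 1810 ± 114 CPM for Mir10b. The mesenchyme and smooth muscle list held 5.70% ± 0.700, with 2.53% on Mir99a. It was led by Mir99a at 25265 ± 4689 CPM, Mir143 at 19685 ± 916 CPM and Mir100 at 5281 ± 840 CPM. Mir122, the only member of the hepatocyte list, held 5.40% ± 0.975. The erythroid list held 2.72% ± 1.45, with Mir451a at 22459 ± 14195 CPM, Mir144 at 3671 ± 525 CPM and Mir486 at 1048 ± 221 CPM. Mir451a, which acts in red cell maturation, and Mir144 lie next to each other on chromosome 11, within 78073005 to 78073241. The erythroid share was 1.69% in replicate 1 and 3.74% in replicate 2, so its SD is large beside its mean.

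The blood leukocyte and megakaryocyte list held 0.722% ± 0.0972 (SD, n = 2) of the sense counts. It was led by Mir223, a myeloid miRNA, at 6256 ± 951 CPM, with Mir181a-1 at 543 ± 43.3 CPM and Mir155 at 234 ± 6.76 CPM. Mir181a-1 shares 20 bases with Mir181a-2 and is uncertain. This share depends on the annotation, because Mir142b is among the genes counted, while Mir142, a miRNA typical of blood cells on the other strand of the same place, is not among those analysed here. Mir142b had 0 sense counts in both libraries, while its opposite strand had 150867 counts in replicate 1 and 144755 in replicate 2. With such opposite-strand counts given to the M21 gene on that strand, an alternative added after the data were seen, Mir142 stood at 38300 ± 1652 CPM, rank 5, and the list held 4.48% ± 0.251.

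**Figure D1:**
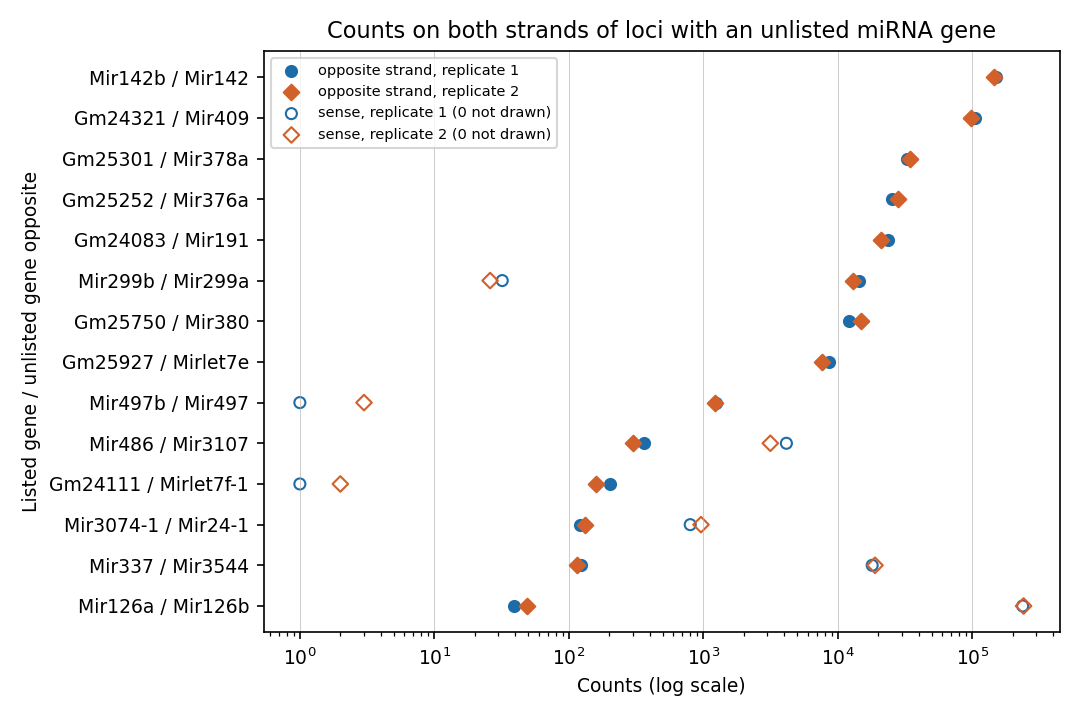
Counts on the opposite strand (filled) and the sense strand (open, 0 not drawn), on a log scale, for 14 loci where a M21 miRNA gene outside the 1973 counted ones lies opposite a counted gene, in replicate 1 (circles) and replicate 2 (diamonds). Opposite-strand counts ran from 39 and 49 at Mir126a to 150867 and 144755 at Mir142b in the 2 replicates.

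**Figure D2:**
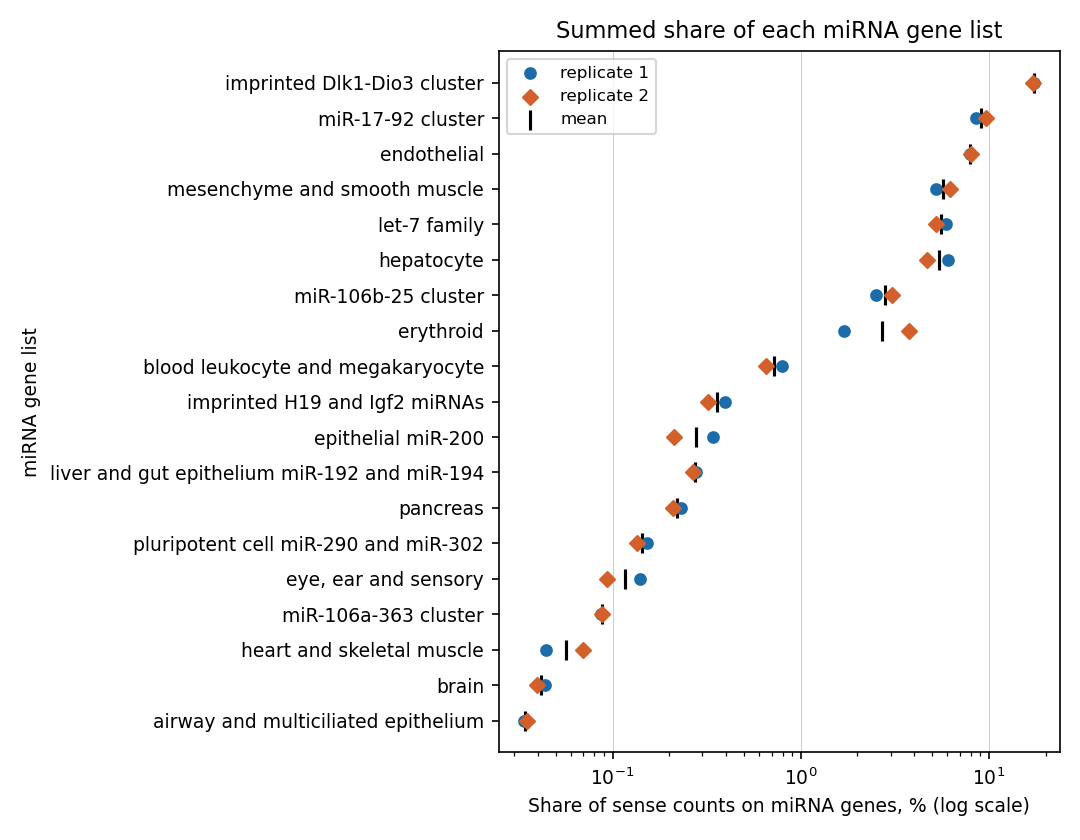
Summed share of sense counts on miRNA genes, in % on a log scale, for each of the 19 lists in replicate 1 (circles) and replicate 2 (diamonds), with the mean as a bar. The imprinted Dlk1-Dio3 list was highest at 17.3%, the airway list lowest at 0.0344%, and the erythroid list lay at 1.69% and 3.74% in the 2 replicates.

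Imprinted miRNAs formed the largest group measured. The Dlk1-Dio3 cluster, expressed from the maternal chromosome, held 17.3% ± 0.183 (SD, n = 2) of the counts, and all 38 listed members reached 10 CPM in both libraries. Its highest members were Mir411 at 23474 ± 1270 CPM, Mir431 at 19822 ± 385 CPM and Mir127 at 17456 ± 326 CPM. They lie in a span of 180 kb on chromosome 12, from 109563692 to 109743795. Mir409, Mir376a, Mir299a and Mir380 of the same region are not among the genes analysed here by sense counts, and with opposite-strand counts given to those genes the cluster held 19.7%. Without genes that share 20 bases, Mir411 among them, it held 14.5%. The imprinted H19 and Igf2 miRNAs held 0.361% ± 0.0527, with Mir483, in an intron of Igf2, at 3436 ± 548 CPM and Mir675, in an exon of H19, at 170 ± 21.1 CPM.

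Members of the same cluster differed widely in counts. How well each miRNA was captured was not measured, so the ratios below need not be ratios of true levels. Their SD covers only the spread over the 2 replicates. The miR-17-92 cluster held 9.06% ± 0.746 (SD, n = 2) of the counts, yet Mir17 exceeded Mir19b-1 by 1070 ± 82.4 times. After Mir17, its highest members were Mir20a at 21484 ± 3445 CPM and Mir92-1 at 9526 ± 830 CPM. Mir92-1 and Mir19b-1 share 20 bases with a second locus, Mir92-1 with Mir92-2, and reads that aligned to several places were not counted, so both levels and this ratio are uncertain. The lowest member without shared bases was Mir19a at 201 ± 0.109 CPM. The paralogous miR-106b-25 cluster, inside Mcm7, held 2.79% ± 0.379, from Mir93 at 16719 ± 2844 CPM through Mir106b at 10083 ± 828 CPM to Mir25 at 1096 ± 116 CPM, a ratio of 15.2 ± 0.992. The miR-106a-363 cluster on chromosome X held 0.0876% ± 0.000584, led by Mir106a at 260 ± 5.95 CPM, Mir92-2 at 255 ± 17.6 CPM and Mir363 at 193 ± 3.20 CPM. The ratio of its highest member to its lowest, Mir19b-2, was 35.9 ± 9.23, but Mir19b-2 shares 20 bases with another locus and is uncertain. Its lowest member without shared bases was Mir18b at 20.2 ± 1.06 CPM. In the cluster of Mir144 and Mir451a, Mir451a exceeded Mir144 by 3.76 times in replicate 1 and 8.04 times in replicate 2. The ratio was 3.28 ± 0.00703 in the miR-183 cluster and 229 ± 49.1 in the Dlk1-Dio3 cluster, where it rests on Mir411 and Mir758, which share bases with each other and are uncertain.

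The let-7 family, which is linked to differentiation, held 5.56% ± 0.509 (SD, n = 2) of the counts. Mirlet7g at 29605 ± 2140 CPM, Mirlet7i at 18262 ± 1365 CPM and Mirlet7d at 3288 ± 921 CPM led it. The 5 members whose hairpin shares no 20 bases with another locus summed to 54480 ± 4922 CPM, and the 5 that share 20 bases summed to 1166 ± 167 CPM. The latter, among them Mirlet7a-1, Mirlet7a-2 and Mirlet7f-2, are uncertain, since reads that fit several loci were left out of the counts.

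Markers of epithelium and of other organs held between 0.0344% and 0.276% of the counts per list. The epithelial miR-200 list held 0.276% ± 0.0914 (SD, n = 2), led by Mir429 at 1408 ± 484 CPM, Mir200c at 686 ± 248 CPM and Mir200b at 422 ± 108 CPM. The list of miR-192 and miR-194, found in liver and gut epithelium, held 0.273% ± 0.00643, with Mir192 at 1801 ± 34.1 CPM and Mir194-2 at 920 ± 31.6 CPM, while Mir194-1 and Mir215 lay at 5.72 ± 1.11 and 4.87 ± 0.319 CPM. The Mir194 copies share 20 bases with each other. The pancreas list held 0.221% ± 0.0159, led by Mir375 at 2194 ± 153 CPM, its only member past 10 CPM in both libraries, while Mir217, Mir216b and Mir216a lay at 9.75 ± 0.982, 4.47 ± 3.12 and 2.73 ± 1.47 CPM. The pluripotent cell list held 0.143% ± 0.0118, led by Mir302a at 440 ± 6.22 CPM, Mir302d at 377 ± 15.2 CPM and Mir302b at 278 ± 52.1 CPM. Mir302a and Mir302b share 20 bases and are uncertain, and without genes that share bases the list held 0.0760%.

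The list for eye, ear and sensory cells, which is the miR-183 cluster, held 0.116% ± 0.0323 (SD, n = 2), with Mir182 at 542 ± 141 CPM, Mir183 at 455 ± 138 CPM and Mir96 at 165 ± 43.4 CPM. The heart and skeletal muscle list held 0.0568% ± 0.0180, led by Mir499 at 266 ± 22.7 CPM, Mir206 at 209 ± 113 CPM and Mir208b at 70.1 ± 43.7 CPM. The brain list held 0.0416% ± 0.00270, led by Mir132 at 138 ± 7.28 CPM, Mir128-1 at 118 ± 14.4 CPM and Mir219a-1 at 82.3 ± 7.26 CPM. Mir128-1 and Mir219a-1 share 20 bases with other copies and are uncertain, and without genes that share bases the brain list held 0.0192%. The airway list held 0.0344% ± 0.000811, with Mir34c at 268 ± 7.03 CPM, Mir449a at 65.3 ± 0.470 CPM and Mir34b at 10.9 ± 0.619 CPM. The 3 listed Mir124a genes of neurons and the muscle genes Mir1a-1, Mir133a-1 and Mir133a-2 had 0 counts in both libraries. Each of these 6 genes shares 20 bases with another copy, so a count of 0 among uniquely aligned reads does not bound the level of the mature miRNA. In all, 9 of 11 brain list genes and 4 of 8 heart and skeletal muscle list genes share 20 bases. The shares of both lists can therefore be too low.

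The 2 replicates ranked the miRNA genes almost alike. Over the 464 genes with at least 10 counts across both libraries, log2(CPM + 1) of the replicates had a Pearson correlation of 0.994 and a Spearman correlation of 0.983. These are correlations across genes, which are not independent replicates. The median absolute log2 ratio was 0.25, and the biological coefficient of variation estimated by edgeR was 0.162. Of the 289 genes with at least 100 counts, 268 differed by less than 1.5-fold and 7 by 2-fold or more.

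**Figure D3:**
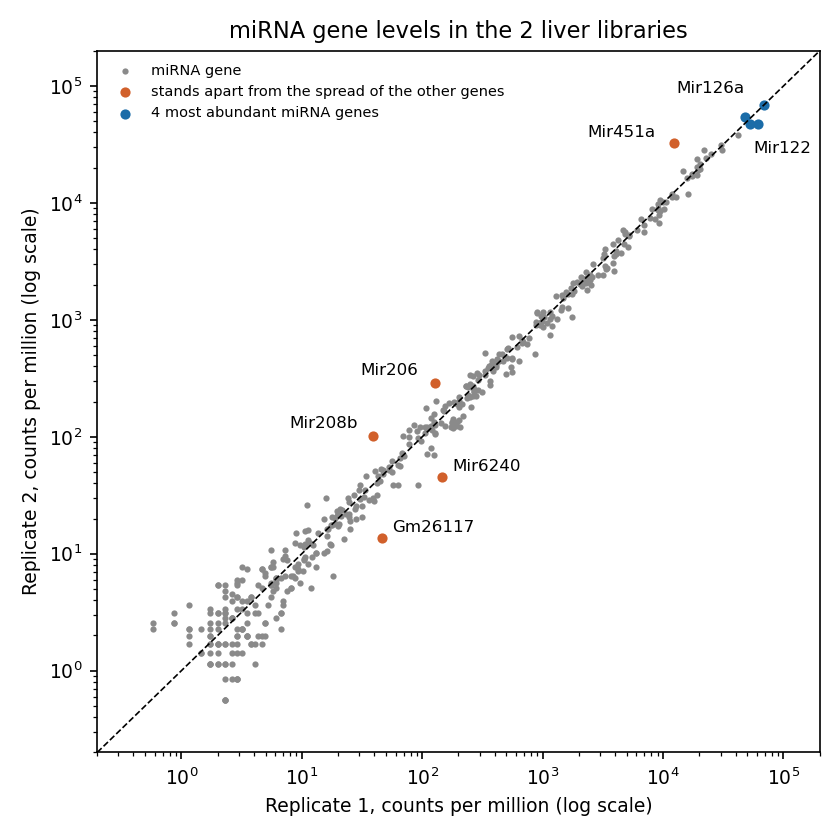
Level of each miRNA gene with counts in both libraries and at least 10 counts in total, in CPM on log axes, replicate 1 against replicate 2, with the line of equal levels dashed. Mir451a, Mir206 and Mir208b lie above the line and Mir6240 and Gm26117 below it, and these 5 genes stood apart from the spread of the other genes, which does not test a difference between replicates.

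Among genes with at least 100 counts that passed the exact binomial test, the erythroid Mir451a had the largest log2 ratio towards replicate 2. On TMM-scaled library sizes, as for all ratios here, Mir451a was 2.72-fold higher in replicate 2, with a log2 ratio of 1.44 (95% interval 1.43 to 1.46). Its CPM, scaled to total sense counts, was 12422 in replicate 1 and 32496 in replicate 2, a log2 ratio of 1.39. The muscle miRNAs Mir208b, in an intron of the myosin gene Myh7, and Mir206 were also higher in replicate 2, with log2 ratios of 1.42 (1.13 to 1.72) and 1.22 (1.06 to 1.38). Mir204, in an intron of Trpm3, had a log2 ratio of 1.28 and Mir196a-2, in an intron of Hoxc5, 0.95. Mir196a-2 shares 20 bases with Mir196a-1. Lower in replicate 2 were Gm26117, in an exon of Adgrb1, with -1.71 (-2.22 to -1.24), Mir6240 with -1.64 (-1.91 to -1.39), and Mir294, of the pluripotent cell list, with -1.19 (-1.49 to -0.90). Mirlet7a-2, an uncertain let-7 copy, and the epithelial Mir200c followed with -0.79 and -0.70.

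These are comparisons of 2 libraries, not of conditions. By a two-sided exact binomial test on TMM-scaled library sizes with Benjamini-Hochberg adjustment, 187 of 464 genes differed, 102 higher and 85 lower in replicate 2, and 29 of the 187 by at least 1.5-fold. The split depended on the scaling, with 77 higher and 101 lower when total counts were used. That test counts any difference beyond counting error. In edgeR's negative binomial exact test, 12 genes passed if a coefficient of variation of 0.1 was assumed, which is below the estimate of 0.162. With the coefficient estimated from these same libraries, 5 genes stood apart from the spread of the others, namely Mir451a, Mir206 and Mir208b above and Mir6240 and Gm26117 below. Of the other genes named for their ratio, Mir204, Mir294, Mirlet7a-2 and Mir200c passed only at 0.1, and Mir196a-2 (adjusted p = 0.0867, edgeR) did not pass there. As each side is 1 library, this ranks genes and does not test a difference.

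By list, the miR-200 and miR-183 genes and most of the let-7 family were lower in replicate 2. All 5 miR-200 genes (5 adjusted over the list alone) passed the exact binomial test as lower, with log2 ratios from -0.70 for Mir200c to -0.47 for Mir200b. All 3 miR-183 genes (3 adjusted over the list alone) were also lower, from -0.57 for Mir183 to -0.48 for Mir182. Genes of 1 cluster share a primary transcript, so their calls are not independent. In the let-7 family 8 of 10 genes (8 adjusted over the list alone) were lower and 0 higher, among them Mirlet7d with -0.52. These directions held under each scaling tried. Mir122 was lower as well, with a log2 ratio of -0.32 (95% interval -0.32 to -0.31), and 1 of 1 passed adjusted over the list alone. In the pluripotent list 3 of 10 genes (3 adjusted over the list alone) were lower, and in the pancreas list 2 of 4 (2 adjusted over the list alone), namely Mir375 with -0.09 and Mir216b with -1.45. In the negative binomial test at an assumed coefficient of variation of 0.1, Mir200c (adjusted p = 0.0344, edgeR), Mirlet7a-2 (adjusted p = 0.0344) and Mir294 (adjusted p = 0.000198) passed among these lists, and Mir122 and the miR-183 genes did not.

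Most mesenchyme list genes and all of miR-106b-25 were higher in replicate 2 in the exact binomial test, and none of them passed the negative binomial test at 0.1. In the mesenchyme list 9 of 11 genes (10 adjusted over the list alone) were higher and 0 lower, for example Mir99a with a log2 ratio of 0.44, Mir100 with 0.38 and Mir143 with 0.15. Scaled to total counts, 6 of the 11 passed. All 3 genes of miR-106b-25 (3 adjusted over the list alone) were higher, with Mir93 at 0.40. In miR-17-92, 3 of 6 were higher and 1 lower (4 adjusted over the list alone), with Mir20a at 0.38, Mir17 at 0.23 and Mir92-1 at -0.12. The erythroid list had 2 higher and 1 lower of 3 (3 adjusted over the list alone), with Mir144 at 0.35 and Mir486 at -0.38. Mir486 overlaps Mir3107 on the other strand, so its level is uncertain. In the heart and skeletal muscle list 3 of 5 (4 adjusted over the list alone) were higher. The 3 endothelial genes (3 adjusted over the list alone) were higher by 0.04 to 0.18, but Mir126a turned to -0.0137 when scaled to total counts. In the negative binomial test at 0.1, Mir451a, Mir206 and Mir208b were the members of these lists that passed.

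In the remaining lists, calls went both ways or few genes passed. The Dlk1-Dio3 cluster had 15 members higher and 13 lower of 38 (29 adjusted over the list alone) and a median log2 ratio of 0.01, which turned to -0.05 when scaled to total counts, with 11 higher and 16 lower. The leukocyte list had 1 higher and 2 lower of 6 (3 adjusted over the list alone), with Mir223 at -0.26. The H19 and Igf2 pair split, with Mir675 at 0.31 and Mir483 at -0.27 (2 adjusted over the list alone). In miR-106a-363, 1 of 6 was higher (1 adjusted over the list alone), and in the brain list 1 of 7 was lower (0 adjusted over the list alone). None of the 4 genes of the miR-192 and miR-194 list and none of the 3 tested airway genes passed over all genes or adjusted over the list alone. Their log2 ratios ran from -0.02 to 0.44 and from 0.07 to 0.17.

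Set against 10000 random lists of equal size and similar level, 8 of 17 lists with at least 3 tested genes had a median log2 ratio outside the central 95%. The heart and skeletal muscle list lay at percentile 100 with a median of 1.22, which fell to 0.70 at the same percentile when only genes with at least 100 counts were used and Mir133b dropped out. Mesenchyme lay at 99.5 with 0.23, miR-106b-25 at 98.4 with 0.27 and the erythroid list at 98.4 with 0.35. The miR-200 list lay at percentile 0 with a median of -0.58, let-7 at 0.28 with -0.22, miR-183 at 0.67 with -0.49 and the pluripotent list at 1.55 with -0.18. For the pluripotent list the median turned to 0.01, at percentile 19.3, once genes with at least 1 count entered, and was -0.35 with at least 100 counts. These percentiles describe the 2 libraries and carry no p-value. The random lists draw each gene separately, while members of a cluster share a primary transcript and can move together. Lists made of clusters, such as miR-183 and miR-106b-25, can therefore fall outside the central 95% more easily. The same holds at least in part for the miR-200, pluripotent and erythroid lists. In these, Mir200b and Mir429 lie close together on chromosome 4, Mir302a, Mir302b and Mir302d on chromosome 3, and Mir144 and Mir451a on chromosome 11.

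**Figure D4:**
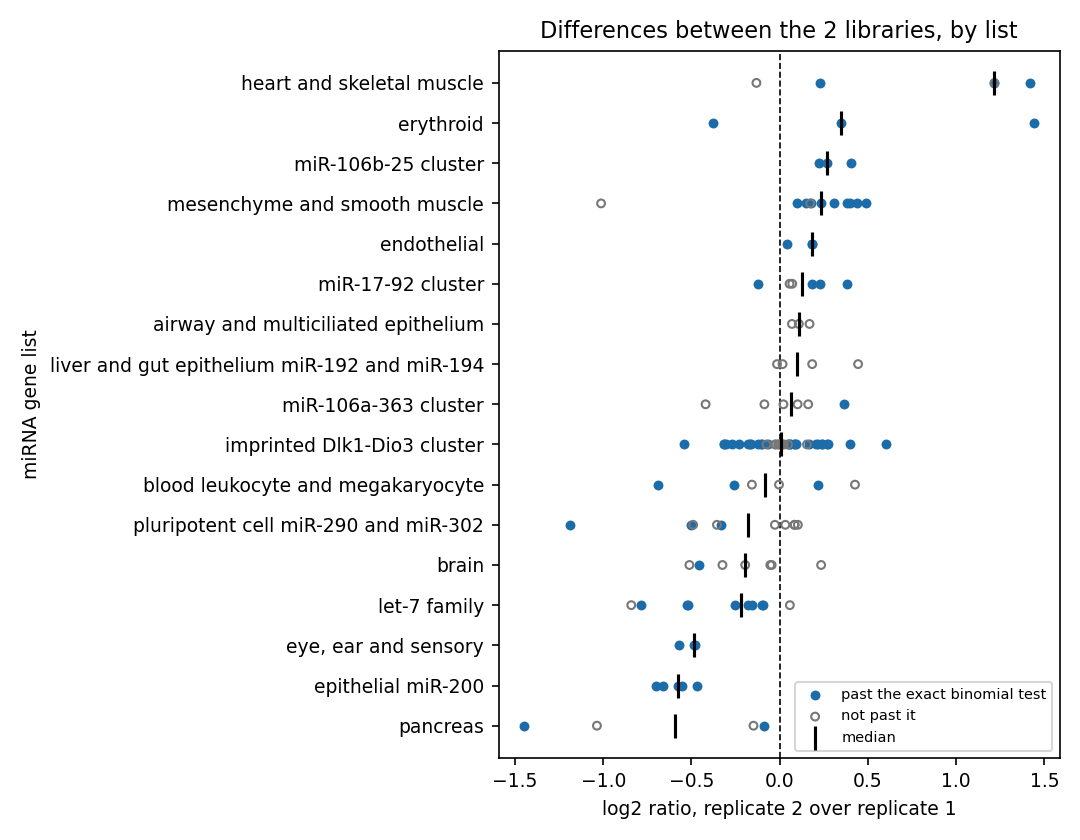
log2 ratio of replicate 2 over replicate 1 for each tested gene of the 17 lists, on TMM-scaled library sizes. Filled points passed the exact binomial test, open points did not, and bars mark list medians, which run from -0.59 for pancreas to 1.22 for heart and skeletal muscle.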

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

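All tests in this part were chosen after the counts had been seen. Opposite-strand counts, which the main values leave out and 2 alternatives include, exceeded what a count of 0 allows and reached 10 CPM in both libraries at 14 loci.

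The largest signal lay opposite Mir142b on chromosome 11 (87756841 to 87756955), with a mean of 147811 counts over the 2 libraries against 0 on the sense strand. Opposite Gm24321 on chromosome 12 the mean was 101458 counts, where M21 places Mir409. The mean was 33531 opposite Gm25301 (Mir378a in M21), 26521 opposite Gm25252 (Mir376a), 22305.5 opposite Gm24083 (Mir191), 13684.5 opposite Mir299b (Mir299a), 13569.5 opposite Gm25750 (Mir380) and 8146 opposite Gm25927 (Mirlet7e). Lower means were found opposite Mir497b with 1238.5 (Mir497), Mir486 with 332 (Mir3107), Gm24111 with 181.5 (Mirlet7f-1), Mir3074-1 with 126.5 (Mir24-1), Mir337 with 120 (Mir3544) and Mir126a with 44 (Mir126b).

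Loss of strand in part of the reads predicts opposite-strand counts at every abundant gene, and over the 10 most abundant genes they made up 0.00338% of counts, at most 0.0184% in a single gene, which argues against it. Reads from miRNA genes of the other strand that are not among the genes analysed here may be the source, since 99.96% of all opposite-strand counts fell on genes that such a M21 gene overlaps. Under that reading Mir142 would rank 5 and Mir409 rank 9 by level. Mir299b, Mir337 and Mir3074-1 carry another identifier version in M21, so their extent in M4 was not checked. No biological explanation was tested.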

How the results depend on the processing

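The alternatives with opposite-strand counts and with an estimated coefficient of variation were chosen after the data were seen. The others were fixed before, except that 20 shared bases stood in for copies of the mature sequence. With both strands counted, the 10 most abundant genes held 38.1%, the 5 liver cell lists together 24.2% (22.5% in the main analysis) and Mir126a stood at 61949 CPM. Opposite-strand counts given to the unlisted gene gave 38.1%, 24.2% and 61940 CPM. Without the top gene the shares were 37.8% and 16.8%, scaled to all reads 12.6% and 7.13% with Mir126a at 21667 per 1000000 reads, and without genes that share 20 bases 44.4% and 25.0% with Mir126a at 76598 CPM. These moves follow from the changed denominators and genes. At 1 CPM, 464 genes were detected in place of 301. A pseudocount of 10 CPM lowered the median absolute log2 ratio to 0.16. The negative binomial test called 12 genes at an assumed variation of 0.1 and 5 at the estimated one, in place of 187; the latter only ranks genes, since the variation comes from the same 2 libraries. Scaled to total counts, the log2 ratio of Mir126a turned to -0.0137. With genes of at least 1 count, where 12 members entered in place of 10, the median of the pluripotent list turned to 0.0104. The added members were Mir290a, with 1 and 4 counts in replicates 1 and 2, and Mir367, with 0 and 4. That turn of the pluripotent median therefore rests on few counts. Each replicate alone gave 306 to 310 detected genes, a top 10 share of 39.4% to 40.3%, a liver list share of 21.7% to 23.3%, Mir126a at 68165 to 68816 CPM and a miR-17-92 ratio of 1012 to 1128. Of the recalculated summary results, 18 moved, as given above, and 56 stayed within 1 SD or 1.5 times. Of the named genes, 39 lost their call at a variation of 0.1 and 43 at the estimated one. No paired analysis was possible because there is 1 group. Depth limits genes near 10 counts, and a coefficient of variation from 2 libraries is itself imprecise.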

Other observations

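The groups and tests in this part were chosen after the values had been seen; the scalings they use were fixed before.

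Further abundant miRNAs belonged to families that the fixed lists did not cover. The cluster on chromosome X from 53047997 to 53054349, with Mir322, Mir503, Mir351, Mir542 and the Mir450 genes, held 3.80% ± 0.0611 (SD, n = 2) of the counts in 7 genes, from Mir322 at 30861 ± 684 CPM to Mir450-2 at 11.4 ± 1.01 CPM. Mir450-1 and Mir450-2 share 20 bases with another locus and are uncertain. The miR-30 family held 3.76% ± 0.0315 in 6 genes, led by Mir30e at 19394 ± 204 CPM and Mir30a at 11903 ± 36.9 CPM. Mir296 and Mir298, at the imprinted Gnas locus on chromosome 2, stood at 4647 ± 604 and 3725 ± 297 CPM. By chromosome, 12 held the largest share of sense counts with 18.2% ± 0.231, ahead of 2 with 11.1% ± 0.0225 and 14 with 10.6% ± 0.802. Chromosome 11 held 9.33% ± 1.46 without the counts opposite Mir142b, so the order after chromosome 12 is uncertain.

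Mir451a, 2.72-fold higher in replicate 2, is a red cell miRNA, and a larger erythroid share in that pool is an obvious biological reading. As the whole cause it would raise Mir144 by about as much, but Mir144 had a log2 ratio of 0.35 (95% interval 0.31 to 0.38) against a bound of 0.72, so it may account for part at most; Mir486, uncertain because Mir3107 overlaps it, had -0.38, and the median of both, -0.0153, adds little as they go opposite ways. Over 4 scalings the lowest log2 ratio of Mir451a was 1.39. A scaling shifts all genes alike and these 4 lie close together, so this shows only that the choice among them mattered little. After a trend on hairpin GC was removed, 1.40 was left. That argues against a trend shared by all genes, but it cannot exclude a bias of this miRNA alone. A change in the stage of the red cells, or in how well this miRNA was captured, may remain and was not tested.

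The 5 miR-200 genes of epithelium and the 3 miR-183 genes of the sensory list were lower together in replicate 2. The median log2 ratio of the 8 genes stayed at or below -0.56 under 4 scalings. As these scalings lie close together, this shows only that the choice among them mattered little. Less pancreatic tissue in that pool cannot be told apart from other causes, since the 4 pancreas list genes had a median of -0.59 but ranged from -0.09 for the abundant Mir375 to -1.45 for Mir216b, which rests on 23 and 8 counts. A smaller hepatocyte share as the whole cause would lower Mir122 by at least as much as the median of the 8 genes. Mir122 fell less, at -0.32 (95% interval -0.32 to -0.31), but beyond the bound of -0.28 set for arguing against such a share. A smaller hepatocyte share may therefore account for part at most and is not excluded. Mir192 and Mir194-2 had a median of 0.00. The sexes and ages of the pooled embryos offer no contrast, so no biological explanation from the design was tested.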
